A study of Mus musculus with 22 samples.

How the data were processed

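RNA of the nucleus accumbens of male C57BL/6J mice (22 libraries, whose titles give a group and a number) was extracted with TRIzol, copied to cDNA with the SMARTer kit, fragmented by sonication and sequenced. The labels name polyA RNA in one field and total RNA as the input of cDNA synthesis in another. The authors aligned reads with STAR 2.4.0 and used FastQC and edgeR, for which no versions are given. The genome build, the annotation and whether counting was stranded are not given in the sources used here, so overlapping and antisense genes are not told apart and no coordinates are reported. Reads aligning to more than 1 place stand in a summary entry and are absent from the genes, so paralogs and pseudogenes are counted from unique reads alone.

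The authors deposited a table of raw read counts with 24066 entries, of which 24061 are genes, and a table of normalised signal with 10874. Per the deposited values, the signal equals each library's counts divided by a single constant per library (largest relative deviation 7.2e-09). That constant is proportional to the library's total count times a factor between 0.934 and 1.03, whose derivation is not given. The raw counts were used throughout. Summary entries (reads outside genes, ambiguous or aligned more than once), which held between 20.6% and 26.4% of a library's counts, were removed first. Of the genes, 4053 had a count of 0 in every library. A spreadsheet had turned 27 gene names into dates. The 24 of these that passed the filter stayed in the tests and counts but are not named. No mitochondrially encoded gene is in the table. Drd1 is listed as Drd1a, and other list genes under older symbols were matched through RefSeq synonyms.

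Analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept with filterByExpr by group (14564 genes), scaled by TMM and fitted in a single 4-group model with robust quasi-likelihood dispersion. Contrasts were tested with the edgeR quasi-likelihood F-test, two-sided, and Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. The contrasts were morphine against saline in water mice and in antibiotic mice, antibiotics against water under saline and under morphine, and the difference between both morphine changes. CPM values use the counts of genes and TMM factors, and log2 CPM a prior count of 2. Labels give no batch, so none was modelled and a batch that follows the groups would not be seen.

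Gene lists for cell types, pathways and treatment-related processes, the comparisons, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. A total of 26 lists with at least 5 measured members were tested in the 5 contrasts with camera (preset correlation 0.01), and Benjamini-Hochberg adjustment ran over all 130 tests. Of these, 55 passed, and 2 of them also passed with an estimated correlation. With fry, which asks whether a list on balance moves one way, 39 of the 130 passed. The erythrocyte list (3 measured genes) and the mitochondrially encoded list (0) were not tested. 9 genes belong to more than 1 list: Cspg4, Gjb6, Homer1, Nfkbia, Pdyn, Penk, Per1, Rorb and Slc16a1. Most lists of other cell types also hold genes that striatal cells express. Named genes are the 12 higher and 12 lower genes with the smallest p per contrast, up to 3 members per list with the smallest p, and 8 reference genes, leaving out systematic clone and predicted names. Some genes this rule selects are not reported here. List counts were also adjusted over the list alone. Library measures and list scores were compared with two-sided exact permutation tests, adjusted over 40 and 104 tests.

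Transcript length, that of the longest protein-coding transcript of each gene, came from the GENCODE annotation held as reference. It was matched by symbol for 13370 of the 14564 genes (91.8%) and was used for the length trend alone. Pairs of libraries were checked for duplicates: within groups, counts of 50 pairs differed by 3.11 to 22.1 times the variance expected of a re-sequenced library. The pipeline was tested on simulated counts with 200 changed genes, using these libraries' sizes and the dispersion of each gene. Genes were drawn independently and trends shared by genes, such as the length slope, were not simulated, so the false calls do not cover them. It recovered 30% of genes changed 1.25-fold, 74% at 1.5-fold, 82% at 2-fold and 96% at 3-fold, with 6 false calls. Alternatives covered normalisation, low-count filter, test, samples in the fit, replicate number as block, a surrogate variable, threshold, dispersion and leaving out each library. Chosen after seeing the data were a score of cortical markers, the share of reads outside genes or the length slope as covariates, leaving out the 2 libraries with the highest Malat1, and the gene set of the authors' normalised table.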

Results

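Messenger RNA of the nucleus accumbens, a region of the ventral striatum that takes part in reward, was counted gene by gene in 22 libraries from male C57BL/6J mice. The mice drank plain water or water with antibiotics that the gut does not absorb, which deplete the gut microbiome, and received saline or morphine. The groups held 6 libraries of water mice given saline, 5 of water mice given morphine, 6 of antibiotic mice given saline and 5 of antibiotic mice given morphine. Total counts ran from 11789713 to 19755139 per library, and the counts assigned to genes from 9357299 to 15330947. Transcripts typical of the tissue were abundant. Penk, which encodes the precursor of enkephalins, averaged 1440 ± 145 CPM (counts scaled to library size; SD, n = 6) in water mice given saline. Pdyn, the precursor of dynorphins, averaged 388 ± 41.9, and the dopamine receptor genes Drd1 (listed as Drd1a) and Drd2 263 ± 36 and 158 ± 23.2. Log2 changes below are given with a standard error, taken as their size divided by the square root of the quasi-likelihood F statistic. P-values measure the spread between these samples, since the titles number the samples but do not state how animals were assigned or pooled.

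The libraries also differed in measures other than single genes. The slope of a library's centred log2 CPM on log2 transcript length averaged 0.0391 ± 0.00743 (SD, n = 5) in water mice given morphine and -0.051 ± 0.0266 (SD, n = 6) in water mice given saline. All 5 morphine libraries lay above all 6 saline libraries (exact permutation test, two-sided, p = 0.00216; adjusted over 40 tests of library measures, 0.0866). Among antibiotic mice the slope averaged 0.0435 ± 0.0112 with morphine and -0.0178 ± 0.0365 with saline (exact p = 0.013, adjusted p = 0.139). A score of cortical and septal neuron markers, which tracks how much neighbouring tissue a piece holds, spread widely inside every group, and its exact p between groups lay between 0.111 and 0.708. In antibiotic mice given saline, library 6 had 15.4% of its counts outside annotated genes, against a group mean of 10.9%, and 2460 CPM of the nuclear RNA Malat1.

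**Figure D1:**
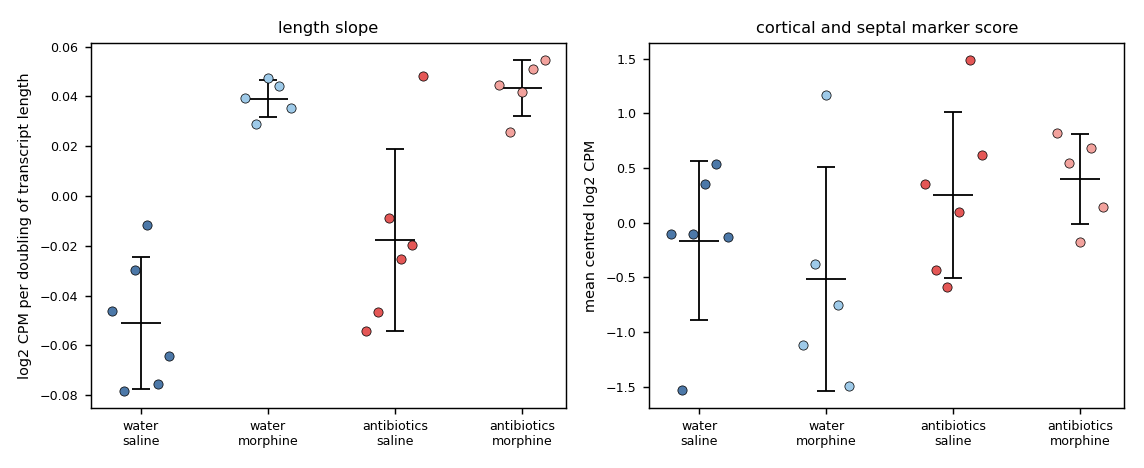
Transcript length slope of each library (change in centred log2 CPM per doubling of transcript length) and score of cortical and septal neuron genes (mean centred log2 CPM), by group, with points for libraries and the mean ± SD. All 5 water libraries with morphine lie above all 6 with saline in length slope, and the marker score overlaps between groups.

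The first comparison asked how repeated morphine (20 mg/kg per day for 7 days) changes the accumbens of mice with an intact microbiome, with 5 morphine and 6 saline libraries. Oprm1, the mu-opioid receptor on which morphine acts, rose 2.06-fold (log2 change 1.04 ± 0.233, adjusted p = 0.0108), from 3.67 ± 0.76 to 7.62 ± 1.81 CPM. Slc9a7, a sodium/proton exchanger of the Golgi, rose 1.68-fold (log2 change 0.75 ± 0.084, adjusted p = 6.58e-05). Gabrb1, a GABA-A receptor subunit, rose 1.54-fold (0.63 ± 0.078) and Erbb4, a neuregulin receptor, 1.75-fold (0.81 ± 0.107). Tenm1, an adhesion protein of synapses, rose 1.98-fold and Vps13c, a lipid transfer protein, 1.47-fold. Among genes that fell, Sepw1, a selenoprotein, had a log2 change of -0.29 ± 0.045 (adjusted p = 0.00101), Napa, a factor that recycles SNARE complexes, -0.25 ± 0.044, and Ppp1r1a, an inhibitor of protein phosphatase 1, -0.45 ± 0.081. Every gene named in these sentences lay on the same side of the saline mean in all 5 morphine libraries.

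Among the gene lists, 30 of the 74 measured nuclear genes of oxidative phosphorylation fell (45 fell when adjusted over the list alone; median log2 change -0.14). Cox7c and Cox4i1, subunits of cytochrome c oxidase, fell by 0.27 ± 0.047 and 0.19 ± 0.037 on the log2 scale. Of 74 cytosolic ribosomal protein genes, 17 fell (49 fell when adjusted over the list alone; median -0.14), among them Rpl28 at -0.22 ± 0.039. Both lists passed the camera test (adjusted p = 5.12e-23 and 3.26e-20), but not with correlation estimated within the list (adjusted p = 0.115 and 0.387 with an estimated correlation). Myelin genes fell at 5 of 24 (15 adjusted over the list alone), with Mbp, the myelin basic protein, at -0.26 ± 0.051. Microglia genes fell at 4 of 23 and rose at 1 (9 and 1 adjusted over the list alone), with the complement gene C1qc at -0.38 ± 0.068. Endothelial genes fell at 4 of 26 (8 adjusted over the list alone), with Cldn5, a tight junction protein, at -0.45 ± 0.096. These 3 lists passed camera (adjusted p = 2.22e-09, 2.31e-07 and 4.72e-05), and again not with estimated correlation (adjusted p = 0.305, 0.387 and 0.314 with an estimated correlation). The striatal projection neuron list also passed camera as lower (median -0.14, adjusted p = 0.0169; adjusted p = 0.722 with an estimated correlation). Of its 28 genes 0 passed in edgeR, DESeq2 or limma-voom (0 adjusted over the list alone), and 1 higher and 2 lower had an unadjusted p under 0.05. Morphine library 4 had a mean centred log2 CPM of -0.377 on this list, and the others of its group -0.0807 to 0.27. Of 23 GABA synapse genes, 3 rose (camera adjusted p = 0.018; adjusted p = 0.469 with an estimated correlation; 3 rose and 1 fell when adjusted over the list alone). Of 8 opioid peptide and receptor genes, 1, Oprm1, passed in edgeR and 2 in DESeq2 and in limma-voom (2 adjusted over the list alone, camera adjusted p = 0.182). Penk (log2 change -0.26 ± 0.15) and Pdyn (-0.04 ± 0.172) did not pass in edgeR. Both values include morphine library 4, with 838 CPM of Penk (others of its group 1270 to 1370) and 228 of Pdyn (392 to 446). Of 22 glucocorticoid-responsive genes 0 passed in edgeR or DESeq2, with 2 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.985).

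In all, 959 of 14564 genes passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 570 higher and 389 lower. The changes were small, with a median size of 0.26 on the log2 scale, and 12 higher and 1 lower gene reached 2-fold. The change ran with transcript length, taken as the longest annotated protein-coding transcript of each gene. Its median was 7766 nt among genes that rose and 1626 nt among those that fell, against 3266.5 nt among all 13370 genes with a known length. With the length slope of each library in the design, chosen after seeing the data, 0 of the 959 genes passed in edgeR (1006 genes had an unadjusted p under 0.05). There Oprm1 had a log2 change of 0.41, the myelin and oxidative phosphorylation lists still passed camera (medians -0.19 and -0.054) and the microglia and ribosomal lists did not. Oprm1 also missed the threshold with replicate number as a block (adjusted p = 0.055). The count was 509, 556, 549 or 615 without morphine library 2 or 6 or without saline library 8 or 4.

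The second comparison put the same question to mice with a depleted microbiome, with 5 morphine and 6 saline libraries. Wnt10b, a secreted Wnt ligand, rose 5.01-fold (log2 change 2.33 ± 0.194, adjusted p = 2.06e-07), from 1.12 ± 0.234 to 5.66 ± 1.2 CPM. Fabp7, a fatty acid binding protein of astrocytes and their precursors, fell to 0.497 of its level (-1.01 ± 0.118, adjusted p = 2.98e-05), from 22 ± 3.9 to 10.9 ± 1.49 CPM. Other genes that rose included Xrn1, an exonuclease that degrades messenger RNA (0.82 ± 0.092), Xpc, a sensor of DNA damage (0.75 ± 0.1), Tet2, which oxidises 5-methylcytosine (0.66 ± 0.095), Ncapd3, a condensin subunit (0.59 ± 0.071), and Rev3l, a translesion polymerase (0.50 ± 0.072). Serpinh1, a collagen chaperone, fell (-0.85 ± 0.115), as did Tufm, a mitochondrial elongation factor (-0.47 ± 0.058), Pex6, a peroxisome factor (-0.55 ± 0.071), Car2, a carbonic anhydrase (-0.42 ± 0.059), and Hexa, a lysosomal enzyme (-0.47 ± 0.065). All of these lay on the same side of the saline mean in all 5 morphine libraries.

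Glucocorticoid-responsive genes rose at 11 of 22 (13 rose when adjusted over the list alone; median 0.35; camera adjusted p = 1.73e-11, adjusted p = 0.087 with an estimated correlation). Fkbp5, a chaperone of the glucocorticoid receptor that the receptor induces, rose by 0.72 ± 0.105, Cdkn1a, a cell cycle inhibitor, by 0.91 ± 0.134, and Arrdc2, an arrestin-like protein, by 0.85 ± 0.139. Microglia genes fell at 16 of 23 (19 adjusted over the list alone; median -0.33; camera adjusted p = 4.21e-15, adjusted p = 0.149 with an estimated correlation), with Fcrls at -0.84 ± 0.123, Olfml3 at -0.90 ± 0.141 and the fractalkine receptor Cx3cr1 at -0.43 ± 0.068. Oligodendrocyte precursor genes fell at 6 of 16 and rose at 1 (7 and 1 adjusted over the list alone), with the lineage factor Olig2 at -0.42 ± 0.083 and the receptor Gpr17 at -0.41 ± 0.065 (camera adjusted p = 0.0391, adjusted p = 0.547 with an estimated correlation). Myelin genes were divided, 4 higher and 4 lower of 24 (4 and 7 adjusted over the list alone; camera adjusted p = 0.0853), with Apod, a lipid carrier, at 0.60 ± 0.126. Oxidative phosphorylation genes fell at 19 of 74 (25 fell and 1 rose when adjusted over the list alone; median -0.10; camera adjusted p = 1.07e-07, adjusted p = 0.484 with an estimated correlation). Ribosomal protein genes fell at 10 of 74 (10 adjusted over the list alone; median -0.09; camera adjusted p = 2.3e-07, adjusted p = 0.562 with an estimated correlation). Oprm1 had a log2 change of 0.38 ± 0.236 that did not pass (adjusted p = 0.311), and its difference from the change in water mice did not pass either (-0.66 ± 0.333, adjusted p = 0.426).

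Here 1900 genes passed, 936 higher and 964 lower, with a median size of 0.28 on the log2 scale. Of these, 15 higher and 6 lower genes reached 2-fold. The longest annotated transcript had a median of 5019.5 nt among genes that rose and 2290 nt among those that fell. With the length slope in the design 138 genes passed, 124 of them among the 1900. Wnt10b and the glucocorticoid and microglia lists passed there, while Fkbp5 and the oxidative phosphorylation and ribosomal lists did not. With only these groups in the fit 1187 genes passed, and 1084, 1101 or 1121 passed without antibiotic-saline library 1, antibiotic-morphine library 1 or antibiotic-morphine library 3.

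The third comparison asked what antibiotics alone change, with 6 libraries in each saline group. Myelin genes fell together: 16 of 24 passed as lower (21 fell when adjusted over the list alone; median log2 change -0.32). Gjb1, the connexin of myelinating cells, fell to 0.607 of its level (-0.72 ± 0.097, adjusted p = 0.001), Ugt8a, which makes the myelin lipid galactosylceramide, to 0.67 (-0.58 ± 0.086), and Trf, the iron carrier transferrin, to 0.69 (-0.54 ± 0.074). The list passed camera with the preset correlation (adjusted p = 2.59e-34) and with an estimated one (adjusted p = 0.0281 with an estimated correlation). Microglia genes fell at 9 of 23 (19 fell and 1 rose when adjusted over the list alone; median -0.25; camera adjusted p = 3.26e-20, adjusted p = 0.087 with an estimated correlation), with Olfml3 at -0.80 ± 0.125 and Csf1r, the receptor on which microglia depend for survival, at -0.25 ± 0.041. Precursor and newly formed oligodendrocyte genes fell at 4 of 16 (5 adjusted over the list alone; camera adjusted p = 0.000698, adjusted p = 0.305 with an estimated correlation), with Olig2 at -0.38 ± 0.077 (adjusted p = 0.0154, and 0.0505 without water library 3). Endothelial genes fell at 2 of 26 (12 fell and 1 rose when adjusted over the list alone; median -0.15; camera adjusted p = 4.95e-05, adjusted p = 0.314 with an estimated correlation).

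Glucocorticoid-responsive genes rose at 4 of 22 (15 rose when adjusted over the list alone; median 0.32; camera adjusted p = 6.73e-14, adjusted p = 0.0802 with an estimated correlation). Plin4, a lipid droplet protein, rose 5.72-fold (2.52 ± 0.432, adjusted p = 0.00792) and Hif3a, a hypoxia-inducible factor, 2.4-fold (1.27 ± 0.23, adjusted p = 0.00986). Fkbp5 was at 0.32 ± 0.103 and did not pass (adjusted p = 0.112). Outside the lists, Rbm3, a cold-induced RNA-binding protein, rose 1.55-fold (0.63 ± 0.087, adjusted p = 0.001) from 56.2 ± 3.47 to 87 ± 14 CPM. Kdm6b, a histone demethylase, rose by 0.46 ± 0.065 and Rasd1, a dexamethasone-induced Ras-like protein, by 1.11 ± 0.208. Gpr37, a receptor of oligodendrocytes, had a log2 change of -0.39 ± 0.061 and Unc5b, a netrin receptor, of -0.50 ± 0.081. Each gene that passed lay on the same side of the water mean in all 6 antibiotic libraries. The cortical and septal marker list had a median of 0.62, with 0 of 20 genes past the threshold in edgeR and 4 in DESeq2 (5 higher and 1 lower at an unadjusted p under 0.05 and when adjusted over the list alone, camera adjusted p = 0.00542, adjusted p = 0.547 with an estimated correlation). Water-saline library 4 had a marker score of -1.53, and the others of its group -0.133 to 0.539. The striatal projection neuron list had a median of -0.23 with 0 of 28 in edgeR or DESeq2 and 2 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.000242, adjusted p = 0.567 with an estimated correlation). Antibiotic-saline library 5 had a mean centred log2 CPM of -0.692 on this list, and the others of its group -0.077 to 0.23.

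In total 205 genes passed, 79 higher and 126 lower, with a median size of 0.32 and 2513 genes at an unadjusted p under 0.05. Of these, 8 higher and 2 lower genes reached 2-fold. The count moved with the libraries and the fit: it was 48, 92 or 96 without antibiotic library 4, 5 or 6 and 409 without antibiotic library 1. It was 59, 108, 118, 131 or 136 without water library 3, 5, 9, 8 or 4. It was 74 without antibiotic-saline library 6 and antibiotic-morphine library 4 together, 67 with only these groups in the fit (Plin4 adjusted p = 0.0717), and 417 with DESeq2. With the length slope in the design 46 genes passed, Plin4 and Hif3a had adjusted p of 0.0665 and 0.0936, and the myelin list passed camera with a median of -0.29.

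The fourth comparison asked what antibiotics change in mice given morphine, with 5 libraries in each group. Glucocorticoid-responsive genes rose together: 17 of 22 passed as higher (19 higher and 1 lower when adjusted over the list alone), with a median log2 change of 0.59. Fkbp5 rose 2.16-fold (1.11 ± 0.112, adjusted p = 2.26e-06), from 62 ± 6.85 to 134 ± 22.2 CPM, Arrdc2 2.79-fold, Cdkn1a 2.54-fold, Sult1a1, a sulfotransferase, 2.91-fold, and Hif3a 4.14-fold. The list passed camera with the preset correlation (adjusted p = 2.99e-25) and with an estimated one (adjusted p = 0.0165 with an estimated correlation). Itgad, an integrin of leukocytes, rose 13.5-fold (3.75 ± 0.41), from 0.211 ± 0.198 to 3.09 ± 0.47 CPM. Wnt10b rose 4.75-fold (2.25 ± 0.199, adjusted p = 3.25e-07) and Rbm3 1.8-fold (0.85 ± 0.093).

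Fabp7 fell to 0.378 of its level (-1.40 ± 0.12, adjusted p = 3.25e-07), and Tubb2b, a tubulin of developing neurons, to 0.596. Microglia genes fell at 17 of 23 (18 adjusted over the list alone; median -0.39; camera adjusted p = 1.87e-17, adjusted p = 0.115 with an estimated correlation), with Olfml3 at -1.46 ± 0.143, Fcrls at -1.18 ± 0.125 and the integrin Itgam at -0.68 ± 0.082. Myelin genes fell at 10 of 24 and rose at 2 (14 and 3 adjusted over the list alone; camera adjusted p = 8.98e-06, adjusted p = 0.473 with an estimated correlation), with Gjb1 at -0.92 ± 0.107 and Ugt8a at -0.91 ± 0.095. Precursor and newly formed oligodendrocyte genes fell at 7 of 16 and rose at 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000201, adjusted p = 0.234 with an estimated correlation), with Olig2 at -0.68 ± 0.084. Astrocyte genes fell at 8 of 20 and rose at 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00752, adjusted p = 0.547 with an estimated correlation), with the water channel Aqp4 at -0.47 ± 0.085 and the amino acid transporter Slc7a10 at -0.56 ± 0.09. GABA synapse genes fell at 5 of 23 (6 adjusted over the list alone; camera adjusted p = 0.0088, adjusted p = 0.387 with an estimated correlation), with the receptor subunit Gabra2 at -0.73 ± 0.1. The cortical and septal marker score averaged 0.403 in these antibiotic libraries and -0.515 in the water libraries (exact permutation p = 0.111). Within both groups, libraries with a higher marker score tended to have a lower mean centred log2 CPM on the GABA synapse list. A part of neighbouring tissue in the lower GABA synapse genes is therefore not excluded. Endothelial genes went both ways, 5 higher and 8 lower of 26 (5 and 8 adjusted over the list alone; camera adjusted p = 0.242): Mfsd2a, a lipid transporter of the blood-brain barrier, rose by 0.80 ± 0.094, and Slco1c1, a thyroxine transporter, had a log2 change of -0.43 ± 0.065.

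This comparison held 2621 genes past the threshold, 1226 higher and 1395 lower, with a median size of 0.32, and 67 higher and 31 lower genes reached 2-fold. The named genes lay on the same side of the water mean in all 5 antibiotic libraries. Length and change were only weakly related (Spearman 0.022 across 13370 genes, which are not independent replicates). With the marker score in the design, chosen after seeing the data, 2950 genes passed, 2091 of them among the 2621.

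**Figure D2:**
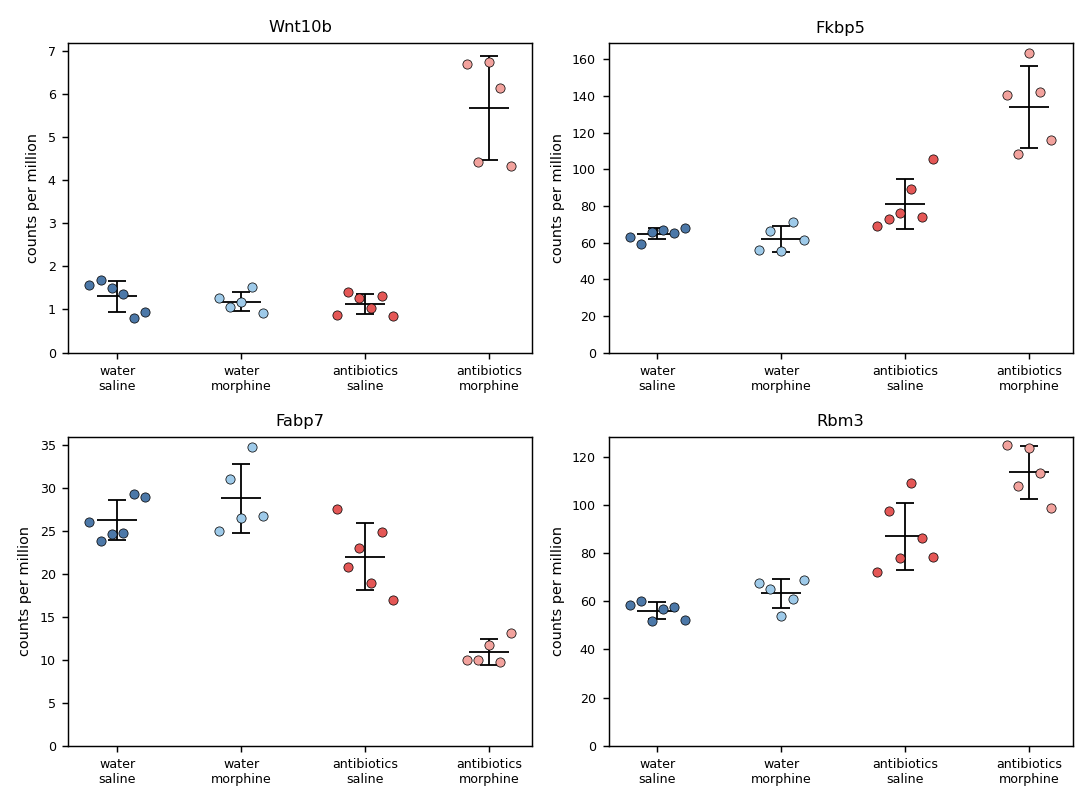
Level of Wnt10b, Fkbp5, Fabp7 and Rbm3 in each library (CPM), by group, with points for libraries and the mean ± SD. Wnt10b averages 5.66 CPM in antibiotic mice given morphine and between 1.12 and 1.3 CPM in the other groups, and Fabp7 averages 10.9 CPM there and between 22 and 28.8 CPM elsewhere.

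Scores per library show the same lists without a model. In water mice the glucocorticoid score (mean centred log2 CPM of the list) averaged -0.339 ± 0.0604 with saline and -0.303 ± 0.0712 with morphine. In antibiotic mice it averaged 0.0987 ± 0.222 and 0.591 ± 0.136. All 6 antibiotic libraries with saline lay above all 6 water libraries with saline (exact permutation p = 0.00216, adjusted over 104 tests 0.0375). All 5 antibiotic libraries with morphine lay above all 5 water libraries with morphine (exact p = 0.00794, adjusted p = 0.0375). Myelin scores lay lower in all 6 antibiotic libraries with saline than in any water library with saline, -0.107 ± 0.114 against 0.237 ± 0.0781, and microglia scores likewise, -0.0244 ± 0.14 against 0.267 ± 0.0524 (exact p = 0.00216 and adjusted p = 0.0375 for each).

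**Figure D3:**
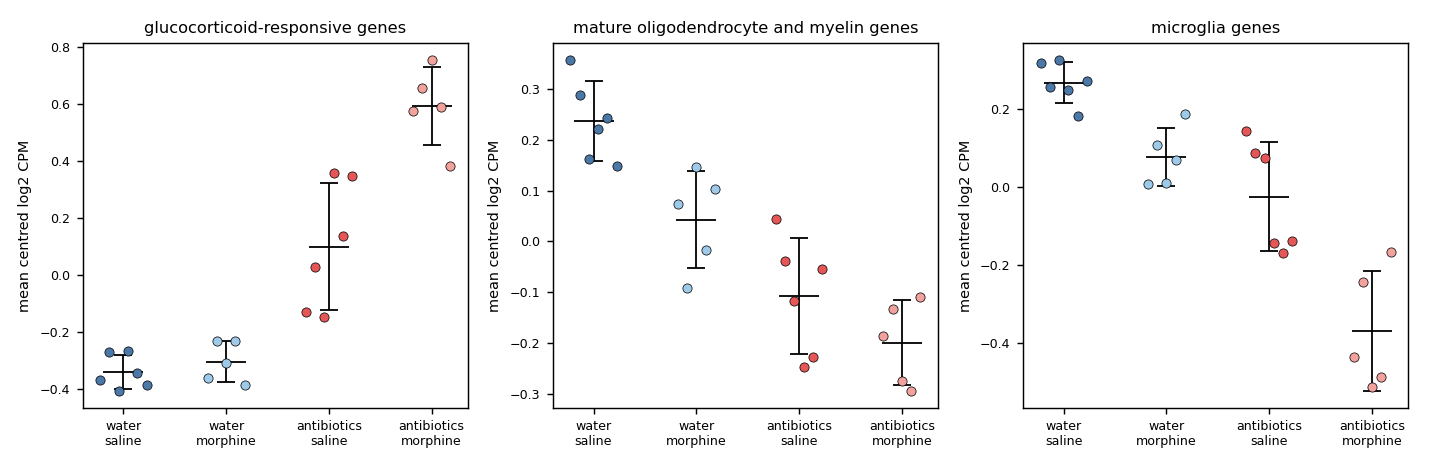
Score of each library (mean centred log2 CPM) for the glucocorticoid-responsive, myelin and microglia lists, by group, with points for libraries and the mean ± SD. Antibiotic libraries lie above the water libraries with the same injection in the glucocorticoid score, and below them in the myelin and microglia scores.

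The interaction asked whether the morphine change differs between antibiotic and water mice, over all 22 libraries. Wnt10b differed most, with a morphine change larger by 2.47 ± 0.301 on the log2 scale in antibiotic mice (adjusted p = 0.000313). The morphine change was also larger for the glucocorticoid-responsive genes Cdkn1a (1.26 ± 0.195, adjusted p = 0.00826), Arrdc2 (1.05 ± 0.205), Map3k6 (0.96 ± 0.19) and Fkbp5 (0.79 ± 0.151), for Mfsd2a (0.68 ± 0.128) and for Pcolce2, a collagen processing enhancer (1.29 ± 0.217). It was lower in antibiotic mice for Fabp7 (-1.15 ± 0.16, adjusted p = 0.00163), Stxbp4, a syntaxin-binding protein (-0.72 ± 0.12), Plxna3, a semaphorin receptor (-0.71 ± 0.123), and Lasp1, an actin-binding protein (-0.42 ± 0.077). Glucocorticoid-responsive genes had larger morphine changes at 4 of 22 (7 adjusted over the list alone), with a median difference of 0.35 (camera adjusted p = 1.73e-11, adjusted p = 0.087 with an estimated correlation). In all 68 genes passed, 32 with a larger and 36 with a lower value in antibiotic mice, and 1791 had an unadjusted p under 0.05. The count fell to 28 without water-morphine library 2, where Fkbp5 (adjusted p = 0.0528), Arrdc2 and Klc3 missed the threshold. It was 177 with DESeq2 and 10 with replicate number as a block, where Fkbp5, Arrdc2, Map3k6, Pcolce2 and Lasp1 missed it.

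Across the 14564 genes, the changes of both morphine comparisons, which share no library, had a Pearson r of 0.27 and a Spearman rho of 0.35, and those of both antibiotic comparisons 0.46 and 0.47. Genes are not independent replicates. Of the genes higher with morphine in water mice, 218 were also higher in antibiotic mice, where 36.6 would be expected if genes were independent, which they are not, and 124 were lower in both, with 25.7 expected. In each direction 4 genes passed with opposite signs. Antibiotics raised 47 genes and lowered 104 in both the saline and the morphine comparison, with 6.65 and 12.1 expected. In edgeR 0 genes passed in both with opposite signs, against 1 with DESeq2 and 29 at an unadjusted p under 0.05.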

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

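The tests with the marker score, the share of reads outside genes or the length slope in the design, the shuffling of the length measure and the slopes of list members were chosen after seeing the data; the splits of the samples were planned.

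Single libraries stood far from the rest of their group in 12 of 84 tests, where chance gives about 1 in 20. In water mice given morphine, library 4 had 4.43 CPM of Oprm1 (others 8 to 8.86), 838 of Penk (1270 to 1370), 228 of Pdyn (392 to 446) and 12.8 of Bdnf (0.58 to 1.95). Library 5 there had 1480 CPM of the ribosomal RNA precursor Rn45s (2120 to 2300). In antibiotic mice given saline, library 6 had 2460 CPM of Malat1 (184 to 368) and 6290 of Rn45s (1650 to 2610). Library 5 there had 138 CPM of Drd1a (239 to 280). In antibiotic mice given morphine, library 4 had 1010 CPM of Malat1 (323 to 492). In water mice given saline, library 6 had 396 CPM of Malat1 (164 to 240), library 4 a cortical and septal score of -1.53 (-0.133 to 0.539) and library 8 0.706 CPM of Itgad (0 to 0.251).

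The morphine change differed between antibiotic and water mice by the test of the difference for 26 named genes. Log2 differences above 0 were 2.468 for Wnt10b, 1.259 for Cdkn1a, 1.286 for Pcolce2, 1.125 for Klc3, 1.05 for Arrdc2, 0.963 for Map3k6, 0.791 for Slc9a2, 0.787 for Fkbp5, 0.693 for AI854517, 0.678 for Mfsd2a, 0.414 for Dbndd2, 0.381 for Trmt6 and 0.381 for Cldn11. Differences below 0 were -1.145 for Fabp7, -0.716 for Stxbp4, -0.714 for Plxna3, -0.691 for Mettl16, -0.621 for Igdcc4, -0.575 for Pycrl, -0.467 for Mtss1l, -0.422 for Gpr17, -0.419 for Lasp1, -0.404 for Tmco3, -0.403 for Specc1, -0.372 for Frmd4a and -0.333 for Caprin1. Lists that passed camera in this contrast had median differences of 0.351 (glucocorticoid-responsive), 0.132 (clock), 0.071 (myelin), 0.045 (oxidative phosphorylation), 0.045 (ribosomal proteins), -0.106 (short-chain fatty acid use), -0.154 (microglia), -0.466 (choroid plexus and ependymal) and -0.498 (fibroblast and meningeal). Their adjusted p lay between 0.087 and 0.767 with an estimated correlation. For the choroid plexus list 0 of 13 and for the fibroblast list 0 of 15 genes passed in edgeR, DESeq2 or limma-voom. Antibiotic-saline library 1 had a fibroblast score of 1.32, and the others of its group -0.168 to 0.12.

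Among 100 splits of the samples of each comparison, the real one included, only the real split called as many genes (1 of 100 each). The real count and the highest other were 959 and 253 for morphine in water mice, and 1900 and 1515 in antibiotic mice. They were 205 and 26 for antibiotics under saline, and 2621 and 468 under morphine. Chance is thus unlikely, but 100 splits cannot show a share below 1 in 100. Such splits do not speak to a batch that follows the groups. For the interaction, antibiotic labels were redrawn within saline and within morphine mice. Of 100 labelings, the real one included, 2 called as many genes (68, highest other 1099). Such redraws also break up the antibiotic change itself, so this share cannot exclude chance for the difference between the morphine changes. A redraw that mostly exchanges these labels under a single injection would itself turn antibiotic changes into an interaction. Which labels the redraw with 1099 genes exchanged was not examined, so that count neither shows nor excludes further structure of the samples. The antibiotic changes correlated as strongly in 3 of 100 redraws, the real one included (real 0.464, highest other 0.484). Chance is unlikely there but not excluded. The morphine changes did so in 18 of 100 (0.269, highest other 0.492), so for these chance stays open.

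Long transcripts rose and short ones fell with morphine in water mice. With the share of reads outside genes in the design 677 of the 959 genes still passed, which argues only weakly against RNA outside genes as the whole cause. That slope was fitted over all 22 libraries, antibiotic-saline library 6 with 15.4% included. The share ran from 9.22% to 10.1% in water mice given saline and from 9.57% to 10.8% with morphine, so the fit tests little within water mice. A length trend between libraries, such as RNA integrity or library preparation could give, cannot be told apart from an effect of morphine, since the slope separates all 5 morphine from all 6 saline libraries: with it in the design 0 of 959 genes passed, as the median change went from 0.26 to 0.13 and the median standard error from 0.065 to 0.104. Within the antibiotic groups, across 916 of the genes, slopes on the length measure correlated with the morphine change in water mice at 0.699, and at 0.463 with length removed, but 15 of 100 redraws with the measure shuffled between libraries of a group gave as high a value (highest other 0.65), so such a gradient is not shown. A biological change of long genes with morphine, which the design names, stays open too.

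Myelin and microglia genes were lower with antibiotics under saline, with a median log2 change of -0.29 over both lists. Endothelial genes had a median of -0.15 there, so lower values were not limited to these cells. More cortical tissue in the antibiotic pieces is argued against as the whole cause by a median of -0.266 with the marker score in the design, and so is the aberrant antibiotic-saline library 6 by a median of -0.273 without it. For myelin genes, the variance of the members' changes was 4.17 times their mean squared standard error, against 1.56 for their slopes on the level of their list within groups. This argues only against a loss of cells that moves all myelin members alike as the whole cause. For microglia genes these ratios were 3.19 and 2.44. The slopes ran from -0.142 to 1.72 for myelin members and from -0.154 to 1.81 for microglia members. A plain loss could therefore move members of either list unequally, and the ratios do not decide on such a loss. Fewer of these cells with members moved unequally was not tested and stays open, whether through loss or through where the piece was cut. For neighbouring tissue only cortical and septal markers were tested. A change of expression within these cells stays open too. Antibiotics may bring about a loss or such a change.

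Glucocorticoid-responsive genes were higher with antibiotics under morphine, with a median log2 change of 0.592. With the marker score in the design the median was 0.623 and with the share of reads outside genes 0.582, which argues against cortical tissue and RNA outside genes as the whole cause. Other neighbouring tissue was not tested. A difference in circulating corticosterone or in glucocorticoid signalling may underlie the pattern, as a hypothesis. Hormone levels were not analysed here, and handling or the time of day at which groups were taken, which the sources used here do not give, stay open.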

How the results depend on the processing

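Settings with the marker score, share of reads outside genes, length slope, the authors' genes or without antibiotic-saline library 6 and antibiotic-morphine library 4 were chosen after seeing the data. Counts stayed within 1.5 times the reported one under all other settings run; the cause was not tested unless given. For morphine in water mice (959) the count was 1623 with a surrogate variable, 1527 with the marker score, 0 with the length slope and 1685 at a threshold of 0.1 (which admits more genes by construction). For morphine in antibiotic mice (1900) it was 138 with the length slope and 1187 with only the groups compared, which leaves fewer libraries. For antibiotics under saline (205) it was 417 with DESeq2, 397 with a surrogate variable, 315 with the marker score, 100 with the share of reads outside genes, 46 with the length slope, 74 without the 2 libraries, 67 with only the groups compared and 518 at 0.1. For the interaction (68) it was 177 with DESeq2, 109 with limma-voom, 201 with a surrogate variable, 161 with the marker score and 146 at 0.1. Replicate numbers do not pair the samples: 25 same-number pairs correlated at 0.002 on average, and 4 of 20 libraries fitted their own number best. With replicate number as a block the counts were 281, 1573, 105, 2003 and 10 in the order of the report, of which 255, 1456, 75, 1890 and 10 were among those reported. Leaving out a library gave 509 to 880 genes for morphine in water mice (509, 556, 549 and 615 without water-morphine 2 and 6 and water-saline 8 and 4). It gave 1084 to 2048 for morphine in antibiotic mice (1084, 1101 and 1121 without antibiotic-saline 1 and antibiotic-morphine 1 and 3). For antibiotics under saline it gave 48 to 409 (48, 92, 96 and 409 without antibiotic-saline 4, 5, 6 and 1; 59, 136, 108, 131 and 118 without water-saline 3, 4, 5, 8 and 9). It gave 1877 to 2748 for antibiotics under morphine and 28 to 100 for the interaction (28, 42 and 41 without water-morphine 2, 3 and 6; 33, 45, 41 and 37 without water-saline 3, 4, 5 and 6; 42 without antibiotic-saline 1; 35 and 30 without antibiotic-morphine 1 and 3). Lists past the threshold numbered 55, 2 with an estimated correlation and 49 to 62 leaving out a library. The correlation of morphine changes (0.269) was 0.492 with the length slope, 0.431 with the authors' genes and 0.198 to 0.324 leaving out a library, and that of antibiotic changes (0.464) 0.421 to 0.513. Reversed with the length slope were the medians of the glutamate receptor list in the first comparison (-0.087), the fibroblast (0.003) and MHC class I (0.064) lists in the second and the ribosomal list in the third (0.041). Reversed genes of the first comparison were Grin2a (-0.223), Gabrg3 (-0.022) and Ep300 (-0.071). Of the named genes that passed, 40 of 53, 63 of 73, 23 of 32, 60 of 75 and 18 of 26 passed without each library in turn, and 32, 61, 20, 60 and 8 under every planned setting. At this depth and sample size small changes are missed: 30% of the smallest simulated changes were recovered.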

Other observations

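The clock hypothesis was tested with genes chosen after the result was seen. The temperature hypothesis followed from the higher Rbm3, and its test on Cirbp was written before the Cirbp values were read.

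Circadian clock genes rose at 5 of 18 in antibiotic mice given morphine against saline (9 adjusted over the list alone; camera adjusted p = 0.000218, adjusted p = 0.0892 with an estimated correlation). They rose at 6 of 18 with antibiotics under morphine (7 adjusted over the list alone; camera adjusted p = 4.43e-05, adjusted p = 0.0802 with an estimated correlation). The repressor genes Cry1, Cry2 and Ciart had log2 changes of 0.51 ± 0.092, 0.36 ± 0.047 and 0.45 ± 0.085 in the latter. The clock list also passed camera with antibiotics under saline (adjusted p = 0.032, adjusted p = 0.387 with an estimated correlation), where 0 of 18 genes passed in edgeR or limma-voom, 3 in DESeq2 and 4 adjusted over the list alone (5 higher and 1 lower at an unadjusted p under 0.05). Genes that sense, carry or use short-chain fatty acids, products of gut bacteria, fell at 5 of 15 with antibiotics under morphine (6 adjusted over the list alone; median -0.30; camera adjusted p = 0.000393, adjusted p = 0.0744 with an estimated correlation). Those that fell were the transporter Slc16a7 and the enzymes Acss2, Oxct1, Mut and Acss1, which activates acetate in mitochondria (-0.81 ± 0.096). Oxct1, an enzyme of ketone use, was at -0.42 ± 0.059 and Mut, an enzyme of propionate use, at -0.30 ± 0.065. This list also passed camera with morphine in antibiotic mice (2 of 15 fell; adjusted p = 0.0141, adjusted p = 0.149 with an estimated correlation). It passed with antibiotics under saline (adjusted p = 0.0136, adjusted p = 0.149 with an estimated correlation), where 0 of 15 genes passed in edgeR or DESeq2, 1 in limma-voom and 4 at an unadjusted p under 0.05. Heat shock and unfolded protein genes fell at 7 of 25 with antibiotics under morphine (8 adjusted over the list alone; camera adjusted p = 0.00216, adjusted p = 0.534 with an estimated correlation), with the chaperone Hsph1 at -0.54 ± 0.071 and the disulfide isomerase Pdia6 at -0.39 ± 0.053. They fell at 5 of 25 with morphine in antibiotic mice (5 adjusted over the list alone; camera adjusted p = 8.09e-05, adjusted p = 0.387 with an estimated correlation). With antibiotics under saline 1 of 25 fell (5 adjusted over the list alone; camera adjusted p = 0.00542, adjusted p = 0.547 with an estimated correlation). With morphine in water mice the list passed camera (adjusted p = 0.00962, adjusted p = 0.547 with an estimated correlation), and 0 of 25 genes passed in edgeR or limma-voom, 1 in DESeq2 and 5 at an unadjusted p under 0.05.

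Interferon-stimulated genes passed camera in no comparison (lowest adjusted p = 0.0515), but 4 of 23 fell with antibiotics under morphine, with Isg15 at -1.17 ± 0.258. MHC class I genes fell at 2 of 15 with morphine in antibiotic mice (camera adjusted p = 0.0402, adjusted p = 0.486 with an estimated correlation). There fibroblast and meningeal genes fell at 2 of 15 (camera adjusted p = 0.0208, adjusted p = 0.582 with an estimated correlation) and mural cell genes at 2 of 13 (camera adjusted p = 0.0327, adjusted p = 0.547 with an estimated correlation). The fibroblast list passed camera as higher with antibiotics under saline (median 0.30, adjusted p = 0.0141; adjusted p = 0.567 with an estimated correlation). Antibiotic-saline library 1 had a fibroblast score of 1.32, the other 5 of that group -0.168 to 0.12, and without it the list passed in neither comparison. Choroid plexus and ependymal genes had a median of 0.48 with antibiotics under saline (camera adjusted p = 0.0391, adjusted p = 0.562 with an estimated correlation). Of these, 0 of 13 passed in edgeR, DESeq2 or limma-voom. Antibiotic-saline libraries 2 and 4 scored 0.865 and 1.1 on this list, and the others of that group -0.527 to 0.292. Immediate early genes passed camera with antibiotics under saline and under morphine (medians 0.20 and 0.23, adjusted p = 0.0108 and 0.0136, or 0.597 and 0.602 with an estimated correlation). In edgeR 0 of 26 passed under saline (2 in DESeq2, 1 in limma-voom) and 2 of 26 under morphine (2 in DESeq2, 4 in limma-voom). Antibiotic-saline library 5 scored 0.684 on this list (others -0.186 to 0.0466) and water-morphine library 6 scored -1.05 (others -0.259 to 0.517). Histone deacetylase and acetyltransferase genes passed camera with antibiotics under saline (median 0.04, adjusted p = 0.0389, adjusted p = 0.387 with an estimated correlation). Of these, 0 of 28 passed in edgeR or limma-voom and 1 in DESeq2, with 7 higher and 0 lower at an unadjusted p under 0.05. Antibiotic-saline library 6 scored 0.127 on this list (others -0.0452 to 0.0375). The lowest camera adjusted p over the 5 contrasts was 0.182 for opioid peptide and receptor genes, 0.275 for striatal interneuron genes, 0.0569 for glutamate receptor genes, 0.0584 for border macrophage and leukocyte genes and 0.126 for inflammatory cytokine and NF-kB target genes.

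Rbm3 and Cirbp both encode RNA-binding proteins induced by mild cold, and a lower brain temperature in antibiotic mice may raise both. Cirbp had a log2 change of 0.256 ± 0.104 with antibiotics under saline, which did not pass (adjusted p = 0.205), and of 0.707 ± 0.112 under morphine, which did (adjusted p = 0.000192), so the test leaves the hypothesis open. Temperature was not analysed here. A shift of circadian phase may be behind the higher clock genes with antibiotics under morphine, in which case Dbp, Per2, Per3, Nr1d1, Nr1d2, Tef and Hlf should move against Arntl, Clock and Npas2. The medians of both sets were 0.114 and 0.114, a difference of 0.001. These sets leave out Per1, Cry1, Cry2 and Ciart, which passed, so the test decides nothing and a phase shift stays open.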
